A study of Neurospora crassa with 86 samples.

How the data were processed

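RNA was sequenced from mycelium of 86 Neurospora crassa cultures in 27 groups of strain and medium, as given by the labels. Fragments per kilobase scaled to the mapped fragments of a library (FPKM) per gene were deposited by the authors for each sample, with confidence bounds, together with a joint table of all samples. Per the submitters' processing notes, HISAT2 2.1.0, Cufflinks 2.2.1 and Cuffnorm 2.2.1 were used. The genome build and the counting options, including strand, are not given in the sources used here, so values of overlapping genes are uncertain. The loci in the per-sample files equalled those of the reference gene table, assembly NC12, for 99.9% of genes, and coordinates are given as in the files. Of 9758 gene identifiers 9757 matched that table, and 1118 had a symbol. The identifier of amn-1, NCU00445, came from background knowledge. A genome sequence and gene products were not used here.

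Each of the 86 columns of the joint table equalled 1 sample's deposited FPKM times 1 factor, with log2 factors from -0.458 to 0.292. The number in the column name differed from the number in the sample label for 51 columns. Columns were therefore used by group, libraries left out in turn are named by their number in the joint table, and analyses by label number used the per-sample values after median-ratio scaling. The joint table held 9598 entries, of which 153 merged neighbouring genes. nit-10 was merged with NCU11348. Its difference between Δnit-2 and wild type in full medium was -1.22 log2 as merged and -5.82 in the per-sample values, so the merged values understate it.

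FPKM are not counts, so no count model was used. Fragments per gene were estimated from the upper bound, taken as FPKM × (1 + 2/√fragments). Under 20 fragments these came out whole (within 0.05) in 78.5% of cases, against 10% by chance, and their sums gave depths of 6890000 to 19100000 fragments per library. Deeper libraries have less counting error. The 100 pairs of replicates held 0 identical pairs, and the lowest chi-square per degree of freedom between replicates was 3.62, so each counted as 1 sample.

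Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the joint table, with 1 mean per group over all 86 samples, a trended prior and Benjamini-Hochberg adjustment over the genes of a comparison. This scale understates differences of low genes. The 8558 genes with FPKM of at least 1 in 3 or more samples were tested, with 59 residual and 3.73 prior degrees of freedom. A gene was called at an adjusted p under 0.05 and a difference of at least 1 log2. All adjusted p of genes are limma's. There were 34 comparisons: 28 between groups and 6 of a deletion's difference between media. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

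Gene lists were tested with limma's camera, two-sided, with a correlation estimated per list and adjustment over the lists of a comparison. Of 28 lists fixed before the data were examined 7 had no member, because they rested on gene products: molybdenum cofactor, catabolism of proline, of branched-chain and of aromatic amino acids, peptidases, proteasome and glycolysis. Of a list for plant cell wall breakdown the members were glycoside hydrolases of any substrate, and of that for peroxisomes and fatty acids peroxins alone, and they are named so. Another 4 lists (proteasome genes by symbol, respiratory complex I, vacuolar ATPase and the quinate cluster) were added after gene names were read and before any test. Lists with fewer than 5 tested members, 7 of them, have counts only. Of 612 list tests 8 passed an adjusted p of 0.05, and 157 with the correlation preset to 0.01; the 8 are among the latter. With the deleted gene left out of the lists 3 passed. Calls adjusted over the list alone equalled those over all genes in 833 of 850 pairs of list and comparison, and both are given where a list described differs.

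The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. As the reference table gave no products, the rule used symbols alone. It took the deleted genes, up to 4 called members per list with the largest differences, a panel of nitrogen genes whether called or not, the 5 highest and lowest called genes with a symbol, a mean of at least 10 FPKM and no overlap between groups, and the called gene with the largest difference. The rule named 1495 pairs of gene and comparison, and 595 were run under the other settings. Of these 47 lost their call when some 1 library was left out, and most of them are not printed.

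The alternatives were a pseudocount of 0.1, no filter on low values (9508 genes), a filter at 10 FPKM (6839 genes), median-ratio scaling, per-sample values (8735 genes), a fit of only the groups compared, the replicate number as a block in a fit of only the groups compared, each library left out in turn, and subsets of the wild type libraries in full medium and without nitrogen by label number. Lists without the deleted gene, ammonium in place of the full medium as reference (for nitrate already a planned comparison), and nitrate in place of the full medium in differences between media for Δnit-2, were added after the data were seen.

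The test was checked on simulated values with the means and spreads of the 8558 genes, without sets of libraries. With 50 genes changed per size, drawn from those with a mean above 3 log2, Δnit-2 against wild type in proline gave calls for 88% at 1.2 log2 and 100% at 1.5, 2 and 3. Nitrogen starvation against full medium gave 96% at 1.2 and 98% at 1.5, with 1 false call. The Δnit-2 difference between proline and full medium gave 78% at 1.2 and 94% at 2, with 2 false calls. In the proline simulation camera called 4 of 100 unchanged lists at an unadjusted p under 0.05.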

Results

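Transcript levels were measured by RNA sequencing in mycelia of the filamentous fungus Neurospora crassa, in 86 libraries from 27 combinations of strain and medium. The wild type gave 47 libraries in 14 media. Deletion strains gave the rest: Δnit-2 15 libraries in 5 media, Δamn-1 12 in 4, and Δnit-4 and Δnmr 6 each in 2. nit-2, nit-4 and amn-1 encode transcription factors and nmr a negative regulator of nitrogen metabolism. Cultures grown for 24 h in sucrose medium were washed and moved for 4 h to a test medium. The reference, called the full medium here, held 2% sucrose and 25 mM ammonium nitrate. Other media lacked nitrogen or carbon, held 2 mM mannose in place of sucrose, or held a single nitrogen source: 50 mM ammonium, nitrate, glutamate, glutamine, isoleucine, proline or tryptophan, 112 mM alanine, 200 mM glycine or 344 mM arginine. Each group held 3 libraries, except wild type in full medium (5) and under nitrogen starvation (6), and the labels describe the replicates as biological. The estimated depth ran from 6890000 to 19100000 fragments per library. Values are FPKM as mean ± SD, and log2 differences are on the scale of log2(FPKM + 1), with the second group subtracted from the first.

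Mitochondrial genes made up 0.0464 to 0.174% of FPKM in all 39 libraries of the ammonium, nitrate, isoleucine, proline and tryptophan media. In the other 47 libraries they made up 0.00297 to 0.0284%. No group had libraries in both ranges, so comparisons of these 5 media with the full medium also compared the ranges, whereas comparisons of strains within a medium did not. Within a range Δnmr and the starved libraries labelled Δnit-4 lay below wild type of their medium without overlap, as did Δamn-1 and Δnit-2 in proline. Within the full medium, wild type libraries 1 to 3 had 0.00858 to 0.00952% and libraries 4 and 5 had 0.0174 to 0.021%. Within nitrogen starvation, wild type libraries 1 to 3 had 0.012 to 0.0148% and libraries 4 to 6 had 0.0245 to 0.0249%.

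**Figure D1:**
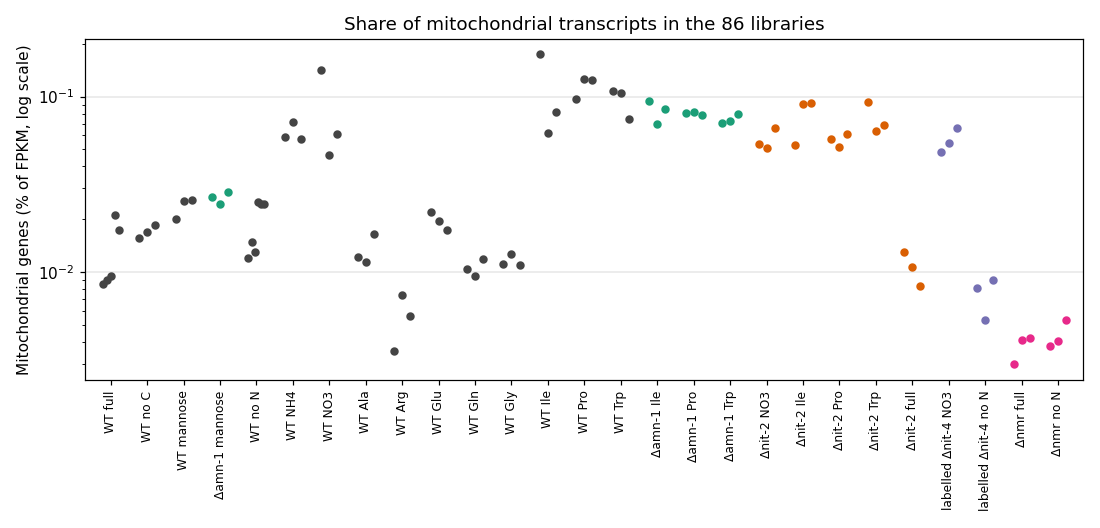
Share of mitochondrial genes in the summed FPKM of each library (vertical log axis, percent) by strain and medium (horizontal axis); each point is 1 library and colours mark the strain. The 39 libraries of the ammonium, nitrate, isoleucine, proline and tryptophan media lie at 0.0464% or above, and the other 47 at 0.0284% or below.

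The deleted genes were read first. nit-2 (NCU09068; supercontig 12.1, 741884 to 746951) lay between 3.30 and 6.61 FPKM in the 15 Δnit-2 libraries and between 14 and 177 in wild type. nmr (NCU04158; supercontig 12.5, 5027349 to 5030561) was at 2.61 ± 0.175 in Δnmr and 13.5 ± 1.2 in wild type in full medium, and at 1.39 ± 0.114 and 18.2 ± 8.24 without nitrogen. NCU00445 (supercontig 12.3, 3886390 to 3890620), taken as amn-1 from background knowledge because the reference table gave it no symbol, was at 0.329 ± 0.0593 in Δamn-1 and 32.4 ± 7.68 in wild type in mannose. In the amino acid media it was at 1.94 ± 0.313 and 12.5 ± 1.19 in isoleucine, 4.63 ± 0.392 and 9.52 ± 0.574 in proline, and 5.11 ± 0.412 and 9.37 ± 0.923 in tryptophan. nit-4 (NCU08294; supercontig 12.4, 2507739 to 2512139) was not lower in the libraries labelled Δnit-4: 6.47 ± 2.1 against 5.31 ± 0.687 in nitrate, and 3.42 ± 0.751 against 3.43 ± 0.644 without nitrogen. FPKM sums a whole gene model and does not show which part of it was read, so this transcript does not check that label, and these are called the libraries labelled Δnit-4.

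In the other strains these genes stayed at measurable levels in each library. Over the wild type media mean nit-2 ran from 14.8 ± 0.948 without carbon to 161 ± 14.8 in arginine, nit-4 from 2.68 ± 0.0561 in glutamate to 8.30 ± 0.236 in tryptophan, nmr from 9.06 ± 0.531 in glutamate to 41.7 ± 10.8 in mannose, and NCU00445 from 7.54 ± 0.129 in glutamate to 32.4 ± 7.68 in mannose. By library, nit-4 was at 2.66 to 13.5 in Δnit-2 and 4.23 to 10.4 in Δamn-1, nmr at 7.73 to 12.8 and 15.5 to 26.1, and NCU00445 at 6.16 to 10.6 in Δnit-2. nit-2 was at 12.2 to 69.1 in Δamn-1. In the Δnmr libraries and those labelled Δnit-4 together, nit-2 was at 23.6 to 48.5 and NCU00445 at 7.37 to 13.4. nmr was at 17.3 ± 1.31 in nitrate and 15.3 ± 1.09 without nitrogen in the libraries labelled Δnit-4, and nit-4 at 3.34 ± 0.406 in full medium and 2.37 ± 0.0557 without nitrogen in Δnmr.

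**Figure D2:**
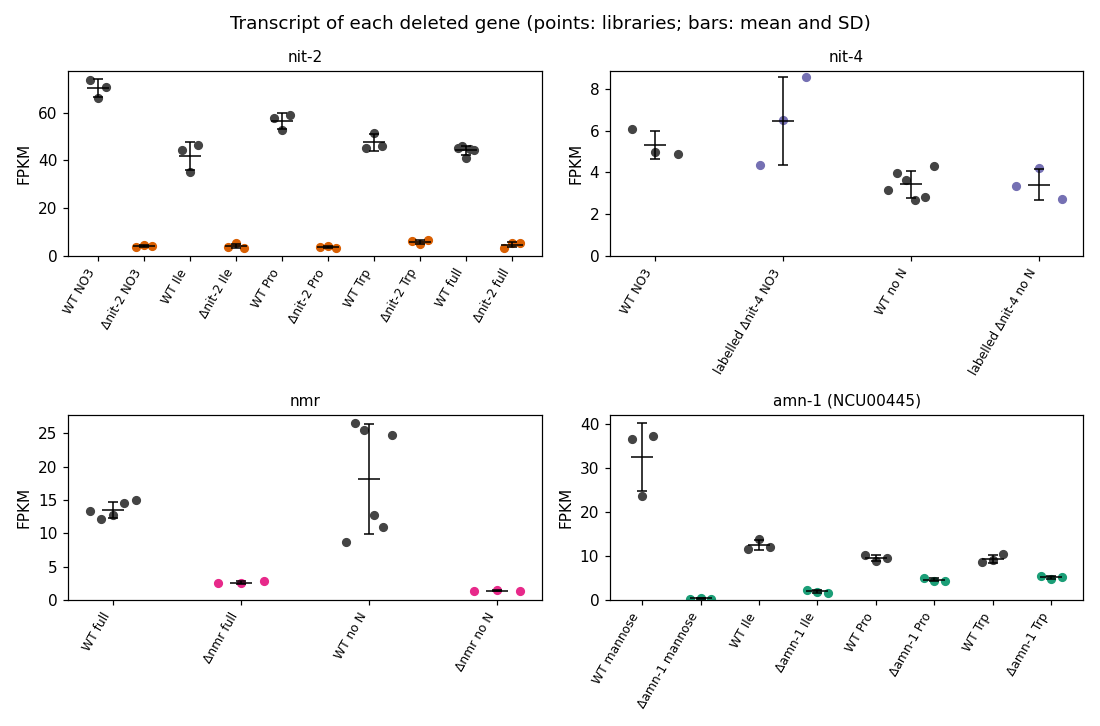
FPKM of nit-2, nit-4, nmr and amn-1 (NCU00445) in each deletion strain and in wild type in the same medium; points are libraries, horizontal marks are group means and bars are SD. nit-2, nmr and NCU00445 were lower in each of their deletion groups than in wild type, and nit-4 was not lower in the libraries labelled Δnit-4.

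**Figure D3:**
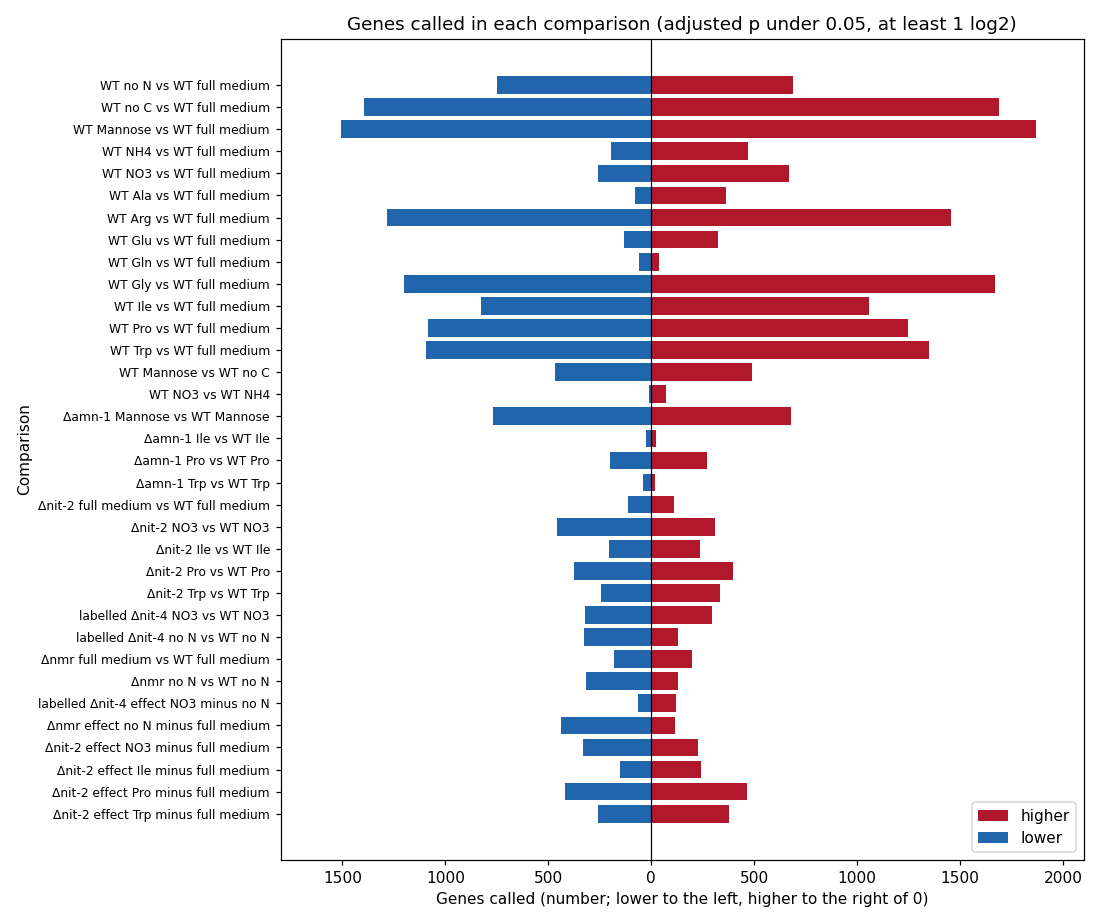
Number of genes called (adjusted p under 0.05 and at least 1 log2) in each of the 34 comparisons, lower to the left and higher to the right of 0 on the horizontal axis. Wild type in mannose against full medium had the most, 3374, and isoleucine in Δamn-1 against wild type the fewest, 50.

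Nitrogen starvation was compared with full medium in wild type (n = 6 and 5). Ammonium assimilation genes moved both ways: am, NADP-dependent glutamate dehydrogenase, fell (633 ± 261 against 1463 ± 146 FPKM; log2 difference -1.30, SE 0.21, adjusted p = 1.2e-07), while gdh-1, the NAD-dependent enzyme, rose (31.0 ± 10 against 10.8 ± 0.686), as did the glutamine synthetase gene gln-2 (1159 ± 370.4 against 349 ± 33.8). pmg, the general amino acid permease, rose (971 ± 293 against 216 ± 16.6) and mtr, the neutral amino acid permease, fell (128 ± 98.6 against 419 ± 34.2), 1 and 1 of 4 amino acid transporters. Of the 63 amino acid biosynthesis genes 42 fell, with ilv-2 (ketol-acid reductoisomerase) at 103 ± 63.5 against 734 ± 83.5; camera gave adjusted p = 0.55 with an estimated correlation. All 10 listed ribosomal protein genes fell (adjusted p = 0.55), po from 1892 ± 129 to 426 ± 198. Both autophagy genes rose (atg-8, 933 ± 173 against 369 ± 60.1; apg-1, 34.2 ± 14.3 against 13.5 ± 1.11), as did aln-1, allantoinase (95.7 ± 43.0 against 22.4 ± 3.48), and xdh-1, xanthine dehydrogenase (43.0 ± 14.7 against 10.7 ± 0.661), 2 of 3 purine and urea genes. Heat shock genes fell in 3 of 10 cases (hsp70-2, 169 ± 51.1 against 1054 ± 109; adjusted p = 0.55). limma called 1441 genes, 690 higher and 751 lower; per-sample values gave 1061 and 592. The starved libraries came in 2 sets by their label numbers: nit-3, nitrate reductase, was at 424 ± 83.1 in libraries 1 to 3 and 4.00 ± 1.48 in 4 to 6, nit-6, nitrite reductase, at 828 ± 179.7 and 5.53 ± 2.91, and the hydrophobin gene eas at 52.9 ± 43.1 and 7251 ± 512 (median-ratio scaled FPKM). nit-3 did not pass over all 6 libraries (-0.14). It was higher by 3.04 with libraries 1 to 3 and lower with 4 to 6 (-3.40). With libraries 1 to 3 alone am (-0.87), gdh-1 (0.88) and apg-1 (0.53) missed the 1 log2 limit.

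Carbon starvation against full medium (n = 3 and 5) gave broader differences. con-6, a conidiation gene, rose from 13.9 ± 11.6 to 7955 ± 1600.5 FPKM (log2 difference 9.72, SE 0.43, adjusted p = 5.3e-30), with eas at 22679 ± 2803 against 52.5 ± 24.4. In all 8 of 14 conidiation genes rose (camera adjusted p = 0.6 with an estimated correlation). gdh-1 rose (350.0 ± 81.6 against 10.8 ± 0.686) and am fell (28.3 ± 4.42 against 1463 ± 146). All 3 nitrate assimilation genes fell, nit-6 to 5.80 ± 1.83, and nit-2 fell (14.8 ± 0.948 against 44.2 ± 1.92). Amino acid biosynthesis fell in 55 of 63 genes (arg-3, carbamoyl-phosphate synthetase, 2.32 ± 0.472 against 102 ± 6.39; adjusted p = 0.36). Glycoside hydrolase genes rose in 28 of 76 cases and fell in 5 (gh28-2, 37.9 ± 7.03 against 0.479 ± 0.111; adjusted p = 0.36), and 5 of 6 sugar transporters rose (cdt-2, a cellodextrin transporter, 27.1 ± 4.86 against 1.65 ± 1.08; adjusted p = 0.36). Peroxin genes rose in 3 of 20 cases (pex11, 138 ± 5.15 against 37.2 ± 4.79; adjusted p = 0.69). Sulfur metabolism genes fell in 9 of 11 cases (cys-14, sulfate permease, 4.20 ± 0.445 against 44.8 ± 4.36; adjusted p = 0.36). 3084 genes were called, 1691 higher and 1393 lower; per-sample values gave 2493 and 1019.

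In mannose against full medium (n = 3 and 5), gdh-1 rose from 10.8 ± 0.686 to 1896 ± 653 FPKM (log2 difference 7.26, SE 0.18, adjusted p = 1.1e-43) and am fell from 1463 ± 146 to 4.83 ± 1.51. NCU00445 (amn-1) rose (32.4 ± 7.68 against 8.23 ± 0.400), as did nmr (41.7 ± 10.8 against 13.5 ± 1.2) and aga-1, arginase (319 ± 107 against 127 ± 7.50). Glycoside hydrolase genes rose in 38 of 76 cases and fell in 4 (gh28-2, 160.4 ± 56.3 against 0.479 ± 0.111), with camera adjusted p = 0.2 at an estimated correlation. hgt-1, a high-affinity glucose transporter, rose (202 ± 46.5 against 23.2 ± 5.92), and glyoxylate and gluconeogenesis genes rose in 4 of 6 cases (acu-6, PEP carboxykinase, 547 ± 214 against 17.8 ± 16.1; adjusted p = 0.62). Amino acid biosynthesis fell in 52 of 63 genes (ilv-2, 5.65 ± 1.78 against 734 ± 83.5; adjusted p = 0.39) and ribosomal proteins in all 10 (crp-10, 105 ± 29.4 against 1067 ± 58.4; adjusted p = 0.4). Of 14 vacuolar ATPase genes 2 rose (adjusted p = 0.57). The count was 3374, 1869 higher and 1505 lower. The median over all genes was 0.136 log2 here and 0.0522 under median-ratio scaling, so differences are relative to that shift.

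Ammonium was compared with the full medium, which holds ammonium and nitrate (n = 3 and 5). nit-3 was at 7.86 ± 1.43 against 48.8 ± 10.6 FPKM (log2 difference -2.48, SE 0.76, adjusted p = 0.005) and the nitrate transporter nit-10, merged with a neighbour in the joint table, at 147 ± 14.6 against 468 ± 93.0; both fell. nit-6 was at 77.1 ± 6.97 against 317 ± 38.3 with adjusted p = 0.046, a call lost when any 1 of the 8 libraries was left out (log2 difference -2.09 to -1.97) and with a pseudocount of 0.1, no filter on low values or full medium libraries 1 to 3 alone. pmg fell (95 ± 18.3 against 216 ± 16.6). Of 7 phosphate uptake genes 2 rose (pho-3, 22.3 ± 5.01 against 1.72 ± 0.486; the phosphate permease pho-4, 20.5 ± 2.83 against 5.93 ± 0.922), and camera called the list (adjusted p = 0.023 with an estimated correlation; 0.00018 to 0.37 under other settings), a call lost when only these 8 libraries were fitted. Heat shock genes rose in 3 of 10 cases (hsp30, 347 ± 108 against 24.1 ± 2.43; adjusted p = 0.83) and conidiation genes in 5 of 14 (ccg-9, 34.0 ± 6.96 against 1.71 ± 0.270; adjusted p = 0.83). limma called 668 genes, 472 higher and 196 lower, and per-sample values gave 283 and 427. The ammonium libraries had 0.057 to 0.0712% mitochondrial FPKM and those of full medium 0.00858 to 0.021%.

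For nitrate against full medium (n = 3 and 5), gln-2 rose (1069.9 ± 96.0 against 349 ± 33.8 FPKM; log2 difference 1.62, SE 0.20, adjusted p = 2.0e-10), as did the basic amino acid permease gene pmb (237 ± 9.95 against 85.2 ± 5.49). nit-3 was at 179.8 ± 17.0 against 48.8 ± 10.6 with adjusted p = 0.031, a call lost without the full medium library numbered 4 in the joint table or any 1 nitrate library (log2 difference 1.81 to 1.99) and with per-sample values or full medium libraries 1 to 3 alone. nit-6 (784 ± 72.3 against 317 ± 38.3) and nit-10 (913 ± 153 against 468 ± 93.0) did not pass, although nit-6 did when only these 8 libraries were fitted. Phosphate uptake genes rose in 3 of 7 cases (pho-3, 20.7 ± 2.33 against 1.72 ± 0.486; camera adjusted p = 0.073 with an estimated correlation), conidiation genes in 7 of 14 (ccg-9, 55.5 ± 8.60 against 1.71 ± 0.270; adjusted p = 0.57) and glycoside hydrolase genes in 8 of 76 (gh38-1, 15 ± 3.13 against 2.56 ± 0.215; adjusted p = 0.98). Of 30 proteasome genes 1 rose (rpn-4, 221 ± 52.7 against 63.6 ± 9.93) and 2 fell (rpn-10, 55.9 ± 6.41 against 144 ± 18.2; adjusted p = 0.98). The count was 930, 671 higher and 259 lower, against 442 and 618 with per-sample values. Mitochondrial FPKM was 0.0464 to 0.141% in nitrate and 0.00858 to 0.021% in full medium. Against ammonium, a comparison given below, 85 genes were called. Of 16 genes called here and chosen by the naming rule 2 were also called in the same direction against ammonium, and hsp30 in the opposite (-1.85). gln-2 (0.85), pmb (0.68), pho-3 (-0.08), ccg-9 (0.70), gh38-1 (0.30), rpn-10 (-0.33) and rpn-4 (0.38) were not.

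Alanine against full medium (n = 3 and 5) raised lao, L-amino acid oxidase, from 33.9 ± 5.41 to 677 ± 32.4 FPKM (log2 difference 4.29, SE 0.41, adjusted p = 2.2e-13). The nitrate genes fell: nit-3 (6.34 ± 0.705 against 48.8 ± 10.6), nit-6 (3.06 ± 0.418 against 317 ± 38.3) and nit-10 (129 ± 6.65 against 468 ± 93.0). Ammonium assimilation genes rose in 3 of 5 cases, gdh-1 (44.6 ± 3.16 against 10.8 ± 0.686), gln-1 (1398 ± 59.8 against 588 ± 29.6) and gln-2 (1418 ± 74.1 against 349 ± 33.8), with camera adjusted p = 0.22 at an estimated correlation. am fell (726 ± 69.3 against 1463 ± 146), a call lost without the full medium libraries numbered 1, 2 or 5 or the alanine library numbered 1 in the joint table (-1.07 to -0.93), with full medium libraries 1 to 3 alone, with median-ratio scaling and with per-sample values. pmg rose (1257 ± 5.33 against 216 ± 16.6). Glyoxylate and gluconeogenesis genes rose in 3 of 6 cases (isocitrate lyase acu-3, 125 ± 11.1 against 53.1 ± 4.60) and phosphate uptake genes in 3 of 7 (pho-4, 25.9 ± 3.22 against 5.93 ± 0.922), each with adjusted p = 0.22. In all 441 genes passed, 364 higher and 77 lower.

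Arginine against full medium (n = 3 and 5) raised both listed arginine catabolism genes, ota, ornithine aminotransferase (1124 ± 107 against 98.5 ± 4.08 FPKM; log2 difference 3.50, SE 0.12, adjusted p = 1.3e-35), and aga-1 (521 ± 77.7 against 127 ± 7.50). nit-6 (1.57 ± 0.377 against 317 ± 38.3), nit-3 (7.84 ± 3.15 against 48.8 ± 10.6) and nit-10 (42.5 ± 4.22 against 468 ± 93.0) fell, while nit-2 (161 ± 14.8 against 44.2 ± 1.92) and nmr (33.9 ± 3.96 against 13.5 ± 1.2) rose, 2 of 7 nitrogen regulators (camera adjusted p = 0.24 with an estimated correlation). Nuclear genes of respiratory complex I fell in 18 of 30 cases (nuo13.4, 27.7 ± 3.94 against 168 ± 11.6; adjusted p = 0.24), and 3 of 14 vacuolar ATPase genes fell (vma-10, 25.6 ± 5.44 against 118 ± 20.3; adjusted p = 0.74). Phosphate uptake rose in 4 of 7 genes (pho-4, 110.4 ± 30.8 against 5.93 ± 0.922; adjusted p = 0.74). Of 5 secondary metabolism genes 1 rose and 1 fell (adjusted p = 0.82). 2739 genes were called, 1455 higher and 1284 lower; per-sample values gave 1064 and 1723.

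Glutamate against full medium (n = 3 and 5) lowered am (342 ± 22.4 against 1463 ± 146 FPKM; log2 difference -2.09, SE 0.25, adjusted p = 3.8e-10) and en(am)-2, glutamate synthase (33.8 ± 2.23 against 102 ± 2.24), and raised gdh-1 (26.2 ± 1.48 against 10.8 ± 0.686) and gln-1 (1279.9 ± 21.5 against 588 ± 29.6). Over this list of 5 ammonium assimilation genes camera gave adjusted p = 0.85 with an estimated correlation. The nitrate genes fell, nit-3 to 1.42 ± 0.158, nit-6 to 0.937 ± 0.235 and nit-10 to 122 ± 4.49. pmg rose (1173 ± 36.5 against 216 ± 16.6). Amino acid biosynthesis fell in 11 of 63 genes, among them his-6 (64.6 ± 4.23 against 194 ± 43.2), with adjusted p = 0.85. pho-4 (48.0 ± 1.27 against 5.93 ± 0.922) and pho-5 (12.7 ± 1.56 against 2.85 ± 0.596) rose, 2 of 7 phosphate uptake genes (adjusted p = 0.65). The test called 458 genes, 326 higher and 132 lower.

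Glutamine gave the fewest calls of the 13 media set against full medium (n = 3 and 5). The nitrate genes fell, nit-3 to 0.685 ± 0.336 FPKM (log2 difference -4.88, SE 0.76, adjusted p = 4.7e-06), nit-6 to 0.905 ± 0.579 and nit-10 to 109 ± 6.22. Ammonium assimilation genes did not pass, with gdh-1 at 11.9 ± 0.840 against 10.8 ± 0.686, gln-1 at 398 ± 33.8 against 588 ± 29.6, gln-2 at 214 ± 44.6 against 349 ± 33.8 and am at 1016 ± 266 against 1463 ± 146. Conidiation genes held 1 lower call of 14, and 2 adjusted over the list alone (camera adjusted p = 0.64 with an estimated correlation). 97 genes were called, 37 higher and 60 lower, and 153 with the smaller pseudocount.

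Glycine against full medium (n = 3 and 5) raised lao from 33.9 ± 5.41 to 5205 ± 214 FPKM (log2 difference 7.23, SE 0.41, adjusted p = 9.4e-25). Both listed glycine and one-carbon genes rose (serine hydroxymethyltransferase, the for gene, 1529.6 ± 92.5 against 594 ± 56.1). gdh-1 (408 ± 48.9 against 10.8 ± 0.686), gln-1 (4139 ± 156 against 588 ± 29.6) and gln-2 (1143 ± 113 against 349 ± 33.8) rose and am fell (654 ± 50.8 against 1463 ± 146). cpc-1, the activator of general amino acid control, rose (5084 ± 271 against 2069.8 ± 152), and so did 37 of 63 amino acid biosynthesis genes (leu-4, 1702 ± 89.2 against 70.4 ± 4.78), with 3 lower (camera adjusted p = 0.72 with an estimated correlation). All 10 ribosomal protein genes fell (crp-2, 203 ± 10.8 against 1374 ± 57.9; adjusted p = 0.51), and 7 of 10 heat shock genes rose (adjusted p = 0.51). Light-responsive genes rose in 6 of 9 cases (al-1, a carotenoid gene, 487 ± 44.5 against 26.6 ± 2.1; adjusted p = 0.35). Citrate synthase cit-1 (58.1 ± 4.47 against 435 ± 20.1), 1 of 2 listed genes of the tricarboxylic acid cycle, fell. In all 2871 genes were called, 1669 higher and 1202 lower, against 1399 and 1504 with per-sample values.

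With isoleucine against full medium (n = 3 and 5), gln-2 rose (1816 ± 226 against 349 ± 33.8 FPKM; log2 difference 2.37, SE 0.20, adjusted p = 1.4e-16) with gdh-1 (42.4 ± 8.67 against 10.8 ± 0.686), and am (306 ± 39.5 against 1463 ± 146) and gln-1 (254 ± 39.4 against 588 ± 29.6) fell. nit-3 (3.09 ± 0.311 against 48.8 ± 10.6), nit-6 (15.7 ± 7.77 against 317 ± 38.3) and nit-10 (107 ± 15.8 against 468 ± 93.0) fell. NCU09773, without a symbol, rose from 1.25 ± 0.402 to 452 ± 127. Amino acid biosynthesis fell in 18 of 63 genes (arg-2, 81.5 ± 10.2 against 345 ± 14.7; camera adjusted p = 0.87 with an estimated correlation). Conidiation genes rose in 6 of 14 cases (ccg-13, 1212 ± 248 against 47.4 ± 33.3; adjusted p = 0.87) and phosphate uptake in 3 of 7 (pho-3, 25.6 ± 1.94 against 1.72 ± 0.486; adjusted p = 0.32). 1882 genes were called, 1056 higher and 826 lower; per-sample values gave 852 and 1150. Mitochondrial FPKM was 0.0617 to 0.174% in isoleucine and 0.00858 to 0.021% in full medium. Against ammonium, chosen as reference after the data were seen, 996 genes were called. NCU09773 (4.18) and gln-2 (1.61) passed, and nit-3 (-1.11), nit-10 (-0.45), gln-1 (-0.30), ccg-13 (1.19) and pho-3 (0.22) did not, and 14 of 22 genes of the naming rule did.

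Proline against full medium (n = 3 and 5) raised gln-2 (2435 ± 80 against 349 ± 33.8 FPKM; log2 difference 2.81, SE 0.20, adjusted p = 8.5e-20) and gdh-1 (40.7 ± 2.13 against 10.8 ± 0.686) and lowered am (360.5 ± 18.1 against 1463 ± 146) and gln-1 (259.6 ± 2.88 against 588 ± 29.6). nit-3, nit-6 and nit-10 fell, to 2.08 ± 0.0674, 17.7 ± 2.63 and 100.4 ± 0.547. NCU09773 rose from 1.25 ± 0.402 to 406 ± 18.9 and the cell wall protein gene ncw-5 from 4.84 ± 1.21 to 563 ± 87.4. Amino acid biosynthesis fell in 22 of 63 genes and rose in 2 (arg-2, 66.8 ± 4.47 against 345 ± 14.7; camera adjusted p = 0.91 with an estimated correlation), and sulfur genes fell in 6 of 11 cases (cys-18, 301 ± 15.6 against 954 ± 78.7; adjusted p = 0.91). Conidiation genes rose in 8 of 14 (ccg-13, 2690.3 ± 255 against 47.4 ± 33.3; adjusted p = 0.91). The count was 2334, 1248 higher and 1086 lower, against 949 and 1498 with per-sample values. Mitochondrial FPKM was 0.0971 to 0.126% in proline. Against ammonium 1485 genes were called. ncw-5 (3.04) and arg-2 (-1.92) passed, and nit-3 (-1.51), nit-6 (-2.07), nit-10 (-0.54), gln-1 (-0.25) and am (-0.89) did not, and 15 of 22 genes of the naming rule did.

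Tryptophan against full medium (n = 3 and 5) raised 5 of 7 genes of the qa cluster for quinate use, among them qa-X (16.5 ± 4.22 against 0.696 ± 0.258 FPKM; log2 difference 3.35, SE 0.18, adjusted p = 5.5e-25), qa-4 (14.1 ± 4.65 against 1.12 ± 0.272) and qa-2 (7.44 ± 3.68 against 1.33 ± 0.247); camera gave adjusted p = 0.056 with an estimated correlation. nit-3, nit-6 and nit-10 fell, to 5.75 ± 1.16, 14.7 ± 2.47 and 67.2 ± 2.65, and nit-4 rose (8.30 ± 0.236 against 3.39 ± 0.268). gln-2 rose (868 ± 38.5 against 349 ± 33.8), whereas am (445 ± 8.63 against 1463 ± 146), gln-1 (167 ± 9.06 against 588 ± 29.6) and pmg (38.6 ± 1.65 against 216 ± 16.6) fell. Amino acid biosynthesis fell in 22 of 63 genes and rose in 3 (met-8, 215 ± 52.4 against 2101 ± 105; ilv-2, 111 ± 2.63 against 734 ± 83.5; adjusted p = 0.81). Light-responsive genes fell in 5 of 9 cases (al-3, 12 ± 0.382 against 30.4 ± 4.74; adjusted p = 0.81), and conidiation genes rose in 8 of 14 (ccg-13, 5214 ± 914 against 47.4 ± 33.3; adjusted p = 0.81). 2445 genes were called, 1349 higher and 1096 lower. Mitochondrial FPKM was 0.0743 to 0.108% in tryptophan. Against ammonium nit-3 (-0.40), nit-10 (-1.11), nit-4 (0.78), gln-1 (-0.88), gln-2 (0.55), am (-0.58) and al-3 (-0.83) were not called, qa-X (2.96) was, and 16 of 25 genes of the naming rule were.

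Mannose and carbon starvation were compared directly (n = 3 each). gdh-1 was higher in mannose (1896 ± 653 against 350.0 ± 81.6 FPKM; log2 difference 2.39, SE 0.20, adjusted p = 1.6e-15) and am lower (4.83 ± 1.51 against 28.3 ± 4.42). Glyoxylate and gluconeogenesis genes were higher in 3 of 6 cases (acu-6, 547 ± 214 against 105 ± 41.1; camera adjusted p = 0.57 with an estimated correlation) and glycoside hydrolase genes in 14 of 76 (gh11-2, 40.6 ± 7.41 against 4.00 ± 0.278; adjusted p = 0.57). The allantoicase gene alc-1 (154 ± 28.6 against 40.6 ± 2.83) and mtr (149 ± 60.8 against 42.5 ± 15.3) were higher, and hsp70-2 (11.8 ± 2.08 against 148 ± 5.39) lower. Of 63 amino acid biosynthesis genes 3 were higher and 5 lower (aro-1, 2.78 ± 0.211 against 14.8 ± 0.695; adjusted p = 0.84). 955 genes were called, 488 higher and 467 lower; per-sample values gave 367 and 732.

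Nitrate against ammonium (n = 3 each) differed in nitrate genes. nit-3 was at 179.8 ± 17.0 against 7.86 ± 1.43 FPKM (log2 difference 4.36, SE 0.85, adjusted p = 5.3e-04) and nit-10 at 913 ± 153 against 147 ± 14.6, both higher in nitrate. nit-6 was at 784 ± 72.3 against 77.1 ± 6.97 with adjusted p = 0.036, and its call was lost when any 1 of the 6 libraries was left out (log2 difference 3.25 to 3.40). npd-1 (nitronate monooxygenase; 53.5 ± 3.78 against 11 ± 1.17), the formate dehydrogenase gene fdh (44.9 ± 3.06 against 7.21 ± 0.505) and pmg (282 ± 32.4 against 95 ± 18.3) were higher, and hsp30 lower (96.7 ± 33.5 against 347 ± 108). Of 10 heat shock genes 2 were lower (camera adjusted p = 0.3 with an estimated correlation). am (762 ± 59.2 against 681 ± 158), gdh-1 (17.1 ± 1.98 against 13.7 ± 1.27) and gln-2 (1069.9 ± 96.0 against 594 ± 74.7) did not pass. 85 genes were called, 74 higher and 11 lower. hsp30 and hsp98, the 2 heat shock genes, were not called when only these 6 libraries were fitted, and hsp98 not without the library numbered 1 of ammonium (-0.93) or 2 of nitrate (-0.94).

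**Figure D4:**
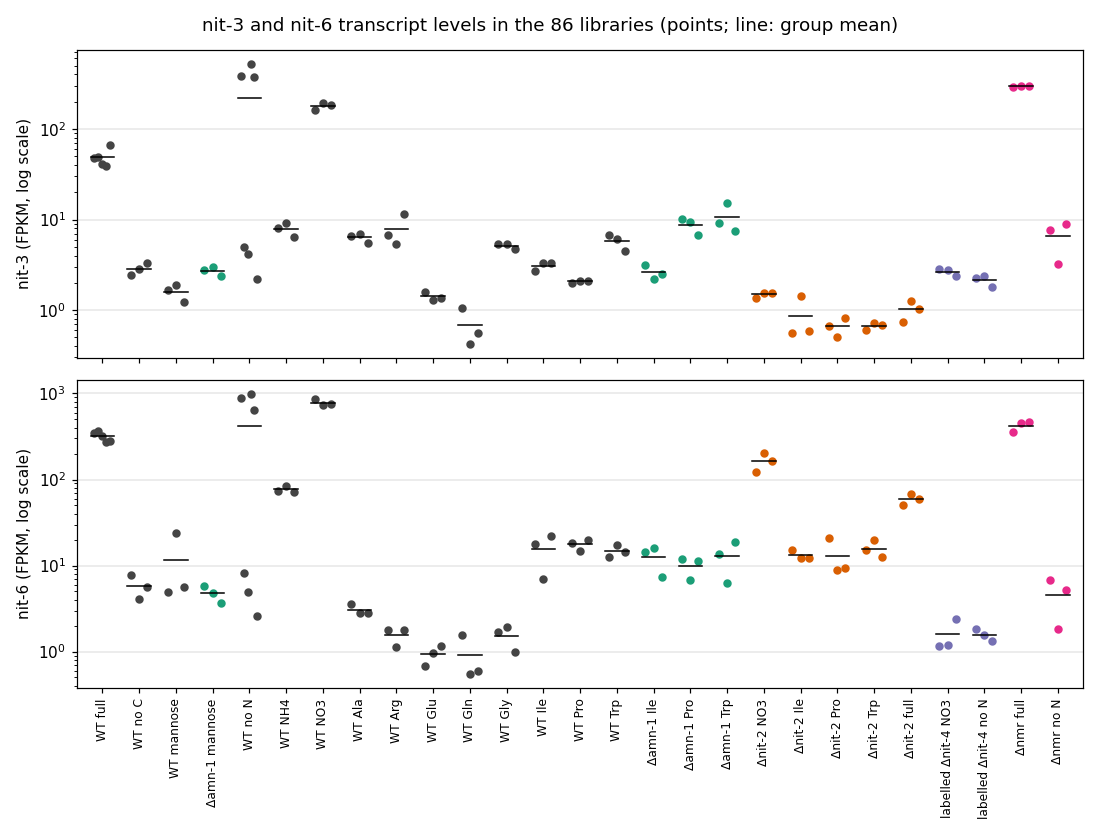
FPKM of nit-3 and nit-6 (vertical log axes) in the 86 libraries by strain and medium (horizontal axis); points are libraries, lines are group means and colours mark the strain. Wild type in nitrate was at 179.8 FPKM for nit-3 and in glutamine at 0.685, and the 6 wild type libraries without nitrogen fell into a higher and a lower set of 3.

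In mannose, Δamn-1 was compared with wild type (n = 3 each), and the deleted gene fell (0.329 ± 0.0593 against 32.4 ± 7.68 FPKM). gdh-1 was lower (409.8 ± 51.8 against 1896 ± 653; log2 difference -2.15, SE 0.20, adjusted p = 4.9e-14) and am higher (30.4 ± 2.83 against 4.83 ± 1.51). mtr (22.9 ± 4.49 against 149 ± 60.8) and alc-1 (46.5 ± 4.89 against 154 ± 28.6) were lower. Ribosomal protein genes were higher in 8 of 10 cases (crp-10, 370.4 ± 37.6 against 105 ± 29.4; camera adjusted p = 0.65 with an estimated correlation) and amino acid biosynthesis genes in 12 of 63, with 4 lower (ilv-2, 37.3 ± 6.57 against 5.65 ± 1.78; adjusted p = 0.74). Glycoside hydrolase genes were lower in 14 of 76 (gh11-2, 3.98 ± 3.21 against 40.6 ± 7.41; adjusted p = 0.65) and conidiation genes in 6 of 14 (adjusted p = 0.71). 1446 genes were called, 677 higher and 769 lower; per-sample values gave 983 and 575.

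In isoleucine the Δamn-1 and wild type libraries differed in few genes (n = 3 each). NCU00445 fell (1.94 ± 0.313 against 12.5 ± 1.19 FPKM; log2 difference -2.20, SE 0.11, adjusted p = 1.1e-25), and NCU02704, without a symbol, was at 0.386 ± 0.287 against 83.8 ± 39.9. nit-3 (2.61 ± 0.484 against 3.09 ± 0.311), gdh-1 (35.6 ± 3.14 against 42.4 ± 8.67), am (282 ± 11.7 against 306 ± 39.5) and gln-2 (1141 ± 221 against 1816 ± 226) did not pass. Nitrogen regulators held 1 lower call of 7, the deleted gene itself. Camera called the list lower (adjusted p = 0.017 with an estimated correlation; 0.0067 to 0.96 under other settings), but not with per-sample values, when only these 6 libraries were fitted, or without the deleted gene (0.96), a test chosen after the data were seen. 50 genes were called, 25 higher and 25 lower, 10 when only these 6 libraries were fitted.

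For proline (n = 3 each), NCU00445 was at 4.63 ± 0.392 against 9.52 ± 0.574 FPKM in Δamn-1 against wild type (log2 difference -0.90, SE 0.11, adjusted p = 6.3e-10), short of the 1 log2 limit, and at -1.03 with a pseudocount of 0.1. am was higher (1204 ± 63.0 against 360.5 ± 18.1) with en(am)-2 (177 ± 13.4 against 84.5 ± 0.975), and 3 of 5 ammonium assimilation genes rose (camera adjusted p = 0.13 with an estimated correlation). lao (1437 ± 204 against 167 ± 21.6) and aln-1 (87.2 ± 7.0 against 31.9 ± 3.57) were higher, and NCU02704 (0.734 ± 0.179 against 29.4 ± 4.25) lower. nit-3 did not pass (8.81 ± 1.79 against 2.08 ± 0.0674), although it did when only these 6 libraries were fitted. limma called 467 genes, 269 higher and 198 lower; per-sample values gave 398 and 123. Mitochondrial FPKM was 0.078 to 0.0818% against 0.0971 to 0.126%.

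In tryptophan (n = 3 each), NCU00445 was at 5.11 ± 0.412 against 9.37 ± 0.923 FPKM (log2 difference -0.76, SE 0.11, adjusted p = 5.3e-07), again short of 1 log2. NCU01830 was lower (2.19 ± 0.249 against 225 ± 34.7), and nit-3 (10.6 ± 4.10 against 5.75 ± 1.16) and am (569 ± 98.6 against 445 ± 8.63) did not pass. Camera called the qa cluster of 7 genes lower (adjusted p = 0.018 with an estimated correlation; 0.00021 to 0.66 under other settings) without a single gene past limma's limits. The call was lost with a pseudocount of 0.1, the filter at 10 FPKM, per-sample values and when only these 6 libraries were fitted. Glycoside hydrolase genes held 2 lower calls of 76 (adjusted p = 0.87), gh10-3 and gh61-9, both lost when only these 6 libraries were fitted. gh10-3 was also lost without the wild type library numbered 1 in the joint table (-0.95), and gh61-9 without wild type 2 (-0.87) or Δamn-1 2 (-0.69) and with per-sample values (-0.97). 55 genes were called, 17 higher and 38 lower, 23 when only these 6 libraries were fitted and 91 without the Δamn-1 library numbered 3 in the joint table.

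In full medium (n = 3 and 5), Δnit-2 had lower am (349.5 ± 32.6 against 1463 ± 146 FPKM; log2 difference -2.06, SE 0.25, adjusted p = 1.6e-09), gln-1 (162 ± 12 against 588 ± 29.6), nit-3 (1.02 ± 0.264 against 48.8 ± 10.6) and alc-1 (33.4 ± 1.74 against 107 ± 7.15) than wild type, with nit-2 at 4.78 ± 1.14 against 44.2 ± 1.92. Camera called the ammonium assimilation list lower (adjusted p = 0.001 with an estimated correlation, 7.4e-05 to 0.19 under other settings; 2 of 5 genes), and the nitrogen regulators (adjusted p = 0.00026, 4e-05 to 0.12 under other settings). Both calls were lost when only these 8 libraries were fitted, and that of the regulators also without the deleted gene (0.083). Nitrate genes held 2 lower calls of 3, and 3 adjusted over the list alone. nit-6 was at 58.9 ± 8.12 against 317 ± 38.3, a call (adjusted p = 0.037) lost without any 1 of the Δnit-2 libraries or the wild type libraries numbered 1 to 3 in the joint table. Phosphate uptake genes rose in 3 of 7 cases (pho-4, 30.6 ± 0.914 against 5.93 ± 0.922; adjusted p = 0.4). NCU01348 was at 0.0746 ± 0.0647 against 55.8 ± 11.5. mfa-1, the mating pheromone precursor of mat a strains, was at 128 ± 5.02 against 1.60 ± 0.342, and matA-1, a mat A mating type gene chosen after its values were seen, was listed at 0 in all 3 Δnit-2 libraries and at 0.772 to 1.01 in wild type. 225 genes were called, 112 higher and 113 lower (116 and 110 with per-sample values), and 365 with the smaller pseudocount.

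Under nitrate (n = 3 each), Δnit-2 had nit-3 at 1.49 ± 0.102 against 179.8 ± 17.0 FPKM (log2 difference -6.18, SE 0.85, adjusted p = 3.5e-08) and nit-10 at 103 ± 6.57 against 913 ± 153, both lower than wild type, with nit-2 at 4.09 ± 0.425 against 70.1 ± 3.78. nit-6 (164 ± 41.8 against 784 ± 72.3) had adjusted p = 0.052 and passed under median-ratio scaling (-2.31), with the stricter filter and when only these 6 libraries were fitted. All 3 nitrate genes were lower adjusted over the list alone. am (226 ± 23.0 against 762 ± 59.2), gln-1 (67.2 ± 2.23 against 311 ± 20.1), aln-1 (8.4 ± 1.19 against 36.8 ± 1.54) and lao (11.2 ± 2.04 against 61.6 ± 13.3) were lower. nmr was lower (8.70 ± 0.667 against 19.7 ± 1.02), but not called with per-sample values. Camera called the nitrogen regulators (adjusted p = 0.0044 with an estimated correlation; 0.00068 to 0.27 under other settings), but not when only these 6 libraries were fitted or without the deleted gene (0.25). Ribosomal protein genes were lower in 9 of 10 cases (po, 623 ± 42.1 against 1739.9 ± 332; adjusted p = 0.49), and glyoxylate and gluconeogenesis genes higher in 3 of 6 (acu-6, 77.5 ± 7.84 against 16.5 ± 4.37; adjusted p = 0.89). NCU01348 was at 1.31 ± 0.204 against 446 ± 97.3. 771 genes were called, 311 higher and 460 lower, against 449 and 289 with per-sample values.

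Isoleucine (n = 3 each) gave lower gln-1 (65.8 ± 5.62 against 254 ± 39.4 FPKM; log2 difference -1.92, SE 0.19, adjusted p = 1.1e-12), am (71.2 ± 13.9 against 306 ± 39.5), pmg (33.4 ± 1.83 against 152 ± 37.7), aln-1 (11.9 ± 5.08 against 60.9 ± 7.79), nmr (8.24 ± 0.723 against 19.6 ± 4.07) and lao (18.5 ± 1.34 against 131 ± 85.0) in Δnit-2 than in wild type, and higher en(am)-2 (177 ± 29.2 against 80.8 ± 5.44). nit-2 was at 4.20 ± 0.988 against 41.8 ± 6.03. Camera called the ammonium assimilation list (adjusted p = 0.044 with an estimated correlation, 0.012 to 0.39 under other settings; 3 of 5 lower, 1 higher) and the nitrogen regulators (adjusted p = 0.015, 0.0089 to 0.74 under other settings). Both calls were lost when only these 6 libraries were fitted and with the deleted gene left out of the regulators (0.087 and 0.74), the former also with the filter at 10 FPKM and the latter with per-sample values. Amino acid biosynthesis was higher in 5 of 63 genes (arg-2, 229.7 ± 32.1 against 81.5 ± 10.2; adjusted p = 0.97). nit-3 (0.863 ± 0.498 against 3.09 ± 0.311) and nit-6 (13.2 ± 1.76 against 15.7 ± 7.77) did not pass, although nit-3 did when only these 6 libraries were fitted, and NCU01348 fell (1.43 ± 0.905 against 1146 ± 367). 445 genes were called, 239 higher and 206 lower.

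Proline (n = 3 each) showed Δnit-2 with nit-2 at 3.81 ± 0.470 against 56.4 ± 3.30 FPKM. lao was lower (16.6 ± 2.66 against 167 ± 21.6; log2 difference -3.26, SE 0.45, adjusted p = 2.7e-08), as were am (101 ± 17.9 against 360.5 ± 18.1), gdh-1 (17.3 ± 2.26 against 40.7 ± 2.13), pmg (61.5 ± 10.3 against 232 ± 27.6), aln-1 (8.32 ± 0.870 against 31.9 ± 3.57) and nmr (8.41 ± 0.793 against 20.5 ± 1.13). Ammonium assimilation genes were lower in 3 of 5 cases (camera adjusted p = 0.25 with an estimated correlation). Biosynthesis genes of amino acids were higher in 7 of 63 genes (arg-2, 245 ± 10.7 against 66.8 ± 4.47; arg-3, 102 ± 20 against 27.6 ± 1.70; adjusted p = 0.99). con-8 was lower (11.3 ± 1.02 against 94.4 ± 25.7), NCU01348 was at 1.44 ± 1.17 against 963 ± 56.0, and nit-3 did not pass (0.663 ± 0.151 against 2.08 ± 0.0674). The test called 773 genes, 399 higher and 374 lower; per-sample values gave 575 and 269. Mitochondrial FPKM was 0.0518 to 0.061% against 0.0971 to 0.126%.

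Tryptophan (n = 3 each) gave Δnit-2 lower gln-1 (31.8 ± 4.26 against 167 ± 9.06 FPKM; log2 difference -2.37, SE 0.19, adjusted p = 2.9e-16), am (81.3 ± 6.12 against 445 ± 8.63), aln-1 (5.65 ± 1.09 against 55.5 ± 5.23) and pmg (5.64 ± 0.249 against 38.6 ± 1.65), with nit-2 at 5.96 ± 0.749 against 47.6 ± 3.53. Ammonium assimilation genes were lower in 2 of 5 cases (camera adjusted p = 0.098 with an estimated correlation). Amino acid biosynthesis was higher in 9 of 63 genes and lower in 1 (his-6, 312 ± 33.7 against 83.9 ± 5.18; arg-2, 235 ± 16.2 against 70.3 ± 5.08; adjusted p = 0.91). NCU01348 fell (2.50 ± 2.19 against 1183 ± 144) and nit-3 had adjusted p = 0.058 (0.665 ± 0.0593 against 5.75 ± 1.16), and passed with the smaller pseudocount and when only these 6 libraries were fitted. 582 genes were called, 336 higher and 246 lower, and 255 and 301 with per-sample values.

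Under nitrate, the libraries labelled Δnit-4 had low nitrate genes (n = 3 each). nit-6 was at 1.59 ± 0.700 against 784 ± 72.3 FPKM (log2 difference -8.27, SE 0.97, adjusted p = 1.7e-09), nit-3 at 2.66 ± 0.255 against 179.8 ± 17.0, nit-10 at 104 ± 4.53 against 913 ± 153 and npd-1 at 3.01 ± 0.744 against 53.5 ± 3.78. pmg (669 ± 23.2 against 282 ± 32.4), aln-1 (96.3 ± 10.1 against 36.8 ± 1.54) and eas (2341 ± 712 against 147 ± 71.0) were higher. Biosynthesis genes of amino acids were lower in 29 of 63 genes (arg-5, 29.7 ± 12.8 against 111 ± 4.97; camera adjusted p = 0.33 with an estimated correlation), and ribosomal proteins in 6 of 10 (adjusted p = 0.59). cpc-1 was lower (628 ± 100.5 against 1470.2 ± 132), but not called with per-sample values. am (448 ± 122 against 762 ± 59.2) and gln-1 (218 ± 36.2 against 311 ± 20.1) did not pass. 616 genes were called, 293 higher and 323 lower; per-sample values gave 484 and 124. Without the library labelled Δnit-4 that is numbered 1 in the joint table the count was 309.

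Without nitrogen, the libraries labelled Δnit-4 (n = 3) were set against the 6 wild type libraries. hsp70-2 was lower (22.6 ± 4.46 against 169 ± 51.1 FPKM; log2 difference -2.80, SE 0.32, adjusted p = 5.6e-10), in 5 of 10 heat shock genes (camera adjusted p = 0.092 with an estimated correlation). Amino acid biosynthesis was lower in 32 of 63 genes (ilv-2, 15.3 ± 3.75 against 103 ± 63.5; aro-1, 6.18 ± 0.643 against 36.6 ± 20.1; adjusted p = 0.1) and ribosomal proteins in all 10 (crp-4, 172 ± 31.0 against 592 ± 283; adjusted p = 0.1). am was lower (216 ± 54.6 against 633 ± 261). nit-6 was at 1.56 ± 0.251 and nit-3 at 2.16 ± 0.312, against 828 ± 179.7 and 424 ± 83.1 in wild type libraries 1 to 3 and 5.53 ± 2.91 and 4.00 ± 1.48 in 4 to 6. With 1 to 3 alone nit-3 differed by -7.10 and nit-6 by -8.35. With 4 to 6 alone nit-6 was called (-1.29) and nit-3 not (-0.66). A fit of only these 9 libraries called neither. 456 genes were called, 129 higher and 327 lower; per-sample values gave 203 and 302. Wild type libraries 1 to 3 alone gave 895, 4 to 6 alone 490 and that fit of 9 libraries 230. Mitochondrial FPKM was 0.00529 to 0.00894% against 0.012 to 0.0249%.

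In full medium (n = 3 and 5), Δnmr had higher lao (491 ± 36.9 against 33.9 ± 5.41 FPKM; log2 difference 3.83, SE 0.41, adjusted p = 2.0e-11), gdh-1 (49.7 ± 1.49 against 10.8 ± 0.686), gln-1 (1284 ± 27.6 against 588 ± 29.6), nit-3 (296 ± 4.00 against 48.8 ± 10.6), pmg (481 ± 15.5 against 216 ± 16.6), aln-1 (57.1 ± 2.25 against 22.4 ± 3.48) and alc-1 (260.2 ± 31.7 against 107 ± 7.15) than wild type, with nmr at 2.61 ± 0.175 against 13.5 ± 1.2. Ammonium assimilation genes rose in 2 of 5 cases (camera adjusted p = 0.057 with an estimated correlation). Nitrate genes held 1 higher call of 3, and 2 adjusted over the list alone. nit-6 (424 ± 59.1 against 317 ± 38.3) and am (1555 ± 81.8 against 1463 ± 146) did not pass. 377 genes were called, 198 higher and 179 lower (178 and 202 under median-ratio scaling), and 588 with the smaller pseudocount. Mitochondrial FPKM was 0.00297 to 0.00417% against 0.00858 to 0.021%.

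Without nitrogen, Δnmr (n = 3) was set against the 6 wild type libraries. fdh was higher (1128 ± 456 against 58.8 ± 35.2 FPKM; log2 difference 4.29, SE 0.27, adjusted p = 4.8e-20), as was acu-6 (482 ± 317 against 46.2 ± 30), and nmr was at 1.39 ± 0.114 against 18.2 ± 8.24. Sulfur metabolism genes were lower in 5 of 11 cases (cys-2, 4.19 ± 1.37 against 34.4 ± 29.6; camera adjusted p = 0.66 with an estimated correlation), and amino acid biosynthesis in 12 of 63 genes (adjusted p = 0.66). nit-3 was at 6.63 ± 3.03 and nit-6 at 4.61 ± 2.54. nit-3 differed by -5.89 from wild type libraries 1 to 3 and by 0.55 from 4 to 6, so its direction turned with the wild type set, and nit-6 differed by -7.32 and -0.25. Neither was called against 4 to 6. mtr was at 383 ± 193 against 128 ± 98.6, and differed by 0.71 from libraries 1 to 3, which was not called. nit-3, nit-6 and mtr were not called in a fit of only these 9 libraries. 448 genes were called, 130 higher and 318 lower, 791 with the smaller pseudocount, 242 in that fit and 1125 against libraries 4 to 6 alone. Mitochondrial FPKM was 0.00377 to 0.00528% against 0.012 to 0.0249%.

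The difference in nitrate was tested against that without nitrogen for the libraries labelled Δnit-4. eas differed by 4.04 in nitrate, and the change between the media was 5.62 (SE 1.32, adjusted p = 0.0041). app had 2.94 and cys-18 -1.19, both past the limits, and nit-3 (-1.81) and nit-6 (-3.51) were not. With wild type starved libraries 1 to 3 alone eas was at 2.01, app at 2.08, nit-3 at 1.45 and cys-18 at -0.85, the last not called. With 4 to 6 alone eas was at 9.36, app at 3.94, cys-18 at -1.41, nit-3 at -4.99 and nit-6 at -7.01, all called. Nitrate genes held 2 lower calls adjusted over the list alone. Of 10 heat shock genes 3 had a higher difference in nitrate (camera adjusted p = 0.57 with an estimated correlation). limma called 187 genes, 122 higher and 65 lower; median-ratio scaling gave 145 and 43, per-sample values 154 and 36. In a fit of only the 4 groups 0 genes were called (1017 at an unadjusted p under 0.05, limma), and wild type starved libraries 1 to 3 or 4 to 6 alone gave 303 and 734. Without the library labelled Δnit-4 numbered 1 in nitrate 96 were called, and 294 without starved wild type 1.

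For Δnmr, the difference without nitrogen was tested against that in full medium. nit-3 had -2.63 without nitrogen and 2.60 in full medium, a change of -5.23 (SE 1.06, adjusted p = 1.5e-04), and nit-6 a change of -4.16. gdh-1 had a change of -2.92, fdh 4.75, mtr 1.89 and cys-2 -1.88, all past the limits. Ammonium assimilation genes had 1 lower call of 5 (camera adjusted p = 0.1 with an estimated correlation) and sulfur genes 5 of 11 (adjusted p = 0.84). Against wild type starved libraries 4 to 6 alone the changes were -2.0 for nit-3 and -0.62 for nit-6, the latter not called. With libraries 1 to 3 alone mtr (0.79) was not called, and in a fit of only the 4 groups nit-3, nit-6, mtr and cys-2 were not. The count was 554, 117 higher and 437 lower, 262 in that fit and 1107 against libraries 4 to 6 alone.

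The Δnit-2 difference in nitrate was tested against that in full medium. aln-1 had a lower difference in nitrate (-1.21, SE 0.34, adjusted p = 0.0064), as did pho-4 (-1.98). eas had a higher one (4.14) and mfa-1 a lower one (-5.18). nit-3 (-1.57) and nit-6 (0.13) did not pass, although nit-3 did in a fit of only the 4 groups. Ribosomal proteins were lower in 6 of 10 cases (camera adjusted p = 0.5 with an estimated correlation), and conidiation genes higher in 2 of 14, 3 adjusted over the list alone (adjusted p = 0.5). 562 genes were called, 229 higher and 333 lower, against 327 and 216 with per-sample values. Here and below Δnit-2 had mfa-1 at 122 to 132 FPKM in full medium and at 1.94 to 5.81 elsewhere. Another strain in full medium would mix strain with medium.

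For isoleucine, NCU09773 had a lower Δnit-2 difference than in full medium (-7.09, SE 0.45, adjusted p = 4.1e-20), and lao (-3.0) and aln-1 (-1.53) were lower too. arg-2 was higher (1.89), with 9 of 63 amino acid biosynthesis genes, 11 adjusted over the list alone (camera adjusted p = 0.6 with an estimated correlation). nit-3 had 3.44, a call lost without Δnit-2 library 2 in isoleucine or 1 in full medium (3.23 to 3.55). 397 genes were called, 244 higher and 153 lower. With nitrate in place of full medium, chosen after the data were seen, 190 were called. NCU09773 (-2.56) and arg-2 (1.10) passed, and aln-1 (-0.31) and lao (-0.24) did not.

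For proline, NCU09773 (-6.95, SE 0.45, adjusted p = 1.1e-19), lao (-3.68) and con-8 (-3.47) had lower Δnit-2 differences than in full medium, and nit-3 (3.71), arg-2 (2.26) and arg-3 (2.14) higher ones. Biosynthesis genes of amino acids were higher in 16 of 63 genes, 17 adjusted over the list alone (camera adjusted p = 0.89 with an estimated correlation). 880 genes were called, 463 higher and 417 lower; per-sample values gave 651 and 291. With nitrate in place of full medium 1023 were called; arg-3 (2.79) and NCU09773 (-2.42) passed, and lao (-0.91) and con-8 (-1.76) did not.

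For tryptophan, NCU09773 (-6.15, SE 0.45, adjusted p = 3.2e-17), lao (-2.76), aln-1 (-2.30) and pmg (-1.71) had lower Δnit-2 differences than in full medium, and arg-2 (2.13) and his-6 (2.0) higher ones. Amino acid biosynthesis was higher in 19 of 63 genes and lower in 1, 23 and 1 adjusted over the list alone (camera adjusted p = 0.89 with an estimated correlation). The count was 640, 380 higher and 260 lower, against 278 and 374 with per-sample values. With nitrate in place of full medium 649 were called. pmg (-1.56) and arg-2 (1.34) passed, and lao (0.00) did not.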

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

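Chosen only after the result was seen were the tests of depth for the starved libraries, all tests of the mitochondrial share, and the tests of the full medium and of loss of nit-2 alone for the mating transcripts.

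In 9 cases 1 library stood far from the others of its group. In wild type in full medium these were gln-1 at 538 FPKM (others 593 to 615), cpc-1 at 1804 (2102 to 2191), cfp at 2461 (3833 to 4570.1), parp at 1.33 (3.82 to 4.98), arg-13 at 14.2 (11.2 to 12), phr at 10.5 (12.1 to 12.4) and qa-X at 1.15 (0.512 to 0.630). Without nitrogen they were xdh-1 at 15.6 (42.1 to 59.4) and fdh at 129 (38.6 to 56.8). Chance gives such a value in about 1 in 20 groups, here 8.85 of 177 tests.

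The wild type starved libraries 1 to 3 and 4 to 6 stood apart, with 1014 of 8705 genes over 1 log2 apart (461 higher in 1 to 3 and 553 in 4 to 6). Depth was higher in 4 to 6, but 13.4% of 5005 genes at 10 FPKM or more were also over 1 log2 apart, where counting error is small. The genes apart had a median aligned difference of -0.01 log2 in full medium libraries 4 and 5 (quartiles -0.17 and 0.16). Depth and mitochondrial share rose there too, so a shared batch is open. Of 74 genes higher in nitrate than in ammonium 10 were higher in 1 to 3 (13.5%, all genes 5.3%). nit-3 and nit-6 were among them, and ammonium may lower others, so leftover nitrate is open. A batch of the starved cultures alone was not tested.

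The mitochondrial share took 2 separate ranges, and 0 groups had libraries in both, so the medium and a library batch cannot be told apart. Depth alone is argued against: among 22 libraries of the lower range with the depth of the higher range the highest share was 0.0257%, and the lowest of the higher range was 0.0464%. If the cells of these media made more respiratory chain, nuclear complex I genes might be higher too; their median difference was 0.11 log2 over 30 genes (quartiles -0.17 and 0.54), which leaves this open.

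In the Δnit-2 libraries of full medium mfa-1 was at 122 to 132 FPKM and matA-1 was listed at 0. The full medium itself is argued against, since mfa-1 reached 1.97 at most in the 8 wild type and Δnmr libraries there, and so is loss of nit-2 alone, with at most 5.81 in the other 12 Δnit-2 libraries. A candidate explanation is another strain of the other mating type in full medium. There 0 of 6 matA-2 and matA-3 values were above 0, but only 5 of 24 were in the other Δnit-2 libraries, which leaves this open. Values chosen after they were seen go with another strain: matA-1 was at 0.296 to 1.85 in the other Δnit-2 libraries, and NCU09968 was at 17.9 to 19.7 in full medium and at 0 to 0.0566 in the others. Joint action of the medium and the deletion was not tested.

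Differences of a strain from wild type were also tested between media. For the libraries labelled Δnit-4, nitrate minus starvation, 187 genes passed, among them eas 5.62, app 2.94, cys-18 -1.19, hsp70-2 1.64 and aln-1 1.11 log2. With wild type starved libraries 1 to 3 alone these were eas 2.01, app 2.08, cys-18 -0.85, hsp70-2 1.68 and aln-1 0.62, cys-18 and aln-1 not called, and with 4 to 6 alone eas 9.36, app 3.94, cys-18 -1.41, hsp70-2 1.71 and aln-1 1.73, all called. With 1 library left out 96 to 294 passed. hsp70-2 lost its call without wild type nitrate 1 or 3, or the libraries labelled Δnit-4 numbered 2 in nitrate or 1 or 3 without nitrogen (1.41 to 1.95). aln-1 lost it without starved wild type 2, 3, 4 or 6, wild type nitrate 1, or the libraries labelled Δnit-4 numbered 1 in nitrate or 2 or 3 without nitrogen (0.99 to 1.32). For Δnmr, starvation minus full medium, 554 passed, with nit-3 -5.23, nit-6 -4.16, gdh-1 -2.92, cys-2 -1.88, mtr 1.89, fdh 4.75 and acu-6 1.82, the last lost without starved Δnmr 1 (acu-6 1.33 to 2.53).

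For Δnit-2 against full medium, 562 genes passed in nitrate, with nit-10 -1.90, aln-1 -1.21, pho-4 -1.98, po -1.26, mfa-1 -5.18 and eas 4.14. nit-10 lost its call without any 1 of 11 of the 14 libraries, all but wild type full medium 1 to 3 (-1.98 to -1.77), and with the per-sample values, in which nit-10 is not merged (-1.59), and po without wild type nitrate 2 (-1.38 to -1.11). In isoleucine 397 passed, with nit-3 3.44, arg-2 1.89, aln-1 -1.53, lao -3.0, con-8 -2.49 and NCU09773 -7.09. nit-3 was lost without Δnit-2 isoleucine 2 or full medium 1 (3.23 to 3.55) and con-8 without Δnit-2 isoleucine 1 (-2.83 to -1.81). Low wild type levels limit nit-3 and NCU09773. In proline 880 passed, with nit-3 3.71, arg-2 2.26, arg-3 2.14, lao -3.68, con-8 -3.47 and NCU09773 -6.95, and in tryptophan 640, with arg-2 2.13, his-6 2.0, aln-1 -2.30, lao -2.76, pmg -1.71 and NCU09773 -6.15.

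Other splits of the same libraries were tested. With 3 against 5 libraries only the real split of 56 reached the real count in 14 comparisons. This argues against chance, not against a batch following the groups. Real counts and the highest of the other splits were 3084 and 1695 for carbon starvation, 3374 and 2045 for mannose, 668 and 192 for ammonium, 930 and 295 for nitrate, 441 and 207 for alanine, 2739 and 1144 for arginine, 458 and 211 for glutamate, 97 and 58 for glutamine, 2871 and 1471 for glycine, 1882 and 751 for isoleucine, 2334 and 1049 for proline, 2445 and 1121 for tryptophan, 225 and 86 for Δnit-2 and 377 and 128 for Δnmr in full medium. Nitrogen starvation gave 1441 and 932 (1 of 100 drawn), likewise. With 3 against 3 the 10 splits cannot give a share under 0.05. These were 955 and 114 for mannose against carbon starvation, 85 and 1 for nitrate against ammonium, 1446 and 128, 50 and 58, 467 and 0 and 55 and 11 for Δamn-1 in mannose, isoleucine, proline and tryptophan, 771 and 25, 445 and 52, 773 and 1 and 582 and 3 for Δnit-2 in nitrate, isoleucine, proline and tryptophan, and 616 and 36 for the libraries labelled Δnit-4 in nitrate.

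Without nitrogen 2 of 84 splits were as large for the libraries labelled Δnit-4 (456 and 849) and 3 of 84 for Δnmr (448 and 882). The splits with 849 and 882 set wild type libraries 1 to 3, and 4 to 6, against the rest. Within those sets the counts were 895 and 490 for the libraries labelled Δnit-4 and 555 and 1125 for Δnmr. For differences between media 100 splits were drawn. As large were 28 for the libraries labelled Δnit-4 (187 and 1501) and 2 for Δnmr (554 and 851). For Δnit-2, nitrate gave 8 (562 and 1082) and isoleucine 9 (397 and 691). Proline gave 1 (880 and 813) and tryptophan 6 (640 and 1018). These draws argue against chance for Δnmr and proline. In nitrate, isoleucine and tryptophan every other split as large kept or exchanged the strains whole in 1 medium and so held a strain difference, and the highest of the rest were 336, 125 and 105, so these splits do not decide. For the libraries labelled Δnit-4 8 of them did, the rest reached 886, and chance is not excluded. The split with 1501 was among those 8.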

How the results depend on the processing

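Chosen after the data were seen were the tests with ammonium as reference (for nitrate also a comparison of its own, fixed before), with nitrate in place of full medium and with the deleted gene left out of the lists. Over all settings without a left-out library 247 of 275 counts of called genes stayed within 1.5 times the main count and 28 did not; with 1 library left out 291 of 295 did. Where a group was left with few libraries, its spread was taken from all groups. Of 4795 values of genes under other settings 4567 kept direction and call, 187 lost the call and 30 gained one. The other 11 changed sign with an adjusted p (limma) under 0.05 before or after the change. These were, with wild type starved libraries 1 to 3 alone, nit-3 (3.04), nit-6 (1.30) and eas (-0.20) in starvation against full medium and nit-3 (1.45, as with a replicate block) in the difference between media of the libraries labelled Δnit-4, and with 4 to 6 alone nit-3 (0.55) in Δnmr without nitrogen. With ammonium as reference they were pho-3 (-0.08), ccg-13 (-0.09) and hsp30 (-1.85) in nitrate and ccg-9 (-0.18) in tryptophan, and with nitrate in place of full medium lao (0.00) in the Δnit-2 difference in tryptophan. For these and the counts below the cause was not tested, except that fits of fewer groups hold fewer samples and take the spread from those groups alone. A pseudocount of 0.1 gave 153 for glutamine, 365 for Δnit-2 and 588 for Δnmr in full medium and 791 for Δnmr without nitrogen. Fits of only the groups compared gave 10 and 23 for Δamn-1 in isoleucine and tryptophan, 230 and 242 for the libraries labelled Δnit-4 and Δnmr without nitrogen, 262 for the Δnmr difference between media and 0 for that of the libraries labelled Δnit-4 (1017 at an unadjusted p under 0.05, limma). Wild type starved libraries 1 to 3 gave 895 for the libraries labelled Δnit-4 and 303 for their difference between media, and 4 to 6 gave 1125 for Δnmr and 734 and 1107 for the differences between media of the libraries labelled Δnit-4 and Δnmr. Ammonium as reference gave 85 for nitrate, 996 for isoleucine and 1485 for proline, and nitrate in place of full medium 190 for the Δnit-2 difference in isoleucine. With 1 library left out the counts ran from 40 to 91 for Δamn-1 in tryptophan (91 without Δamn-1 library 3), 309 to 848 for the libraries labelled Δnit-4 in nitrate (309 without their library 1) and 96 to 294 for their difference between media (96 without that library, 294 without starved wild type library 1).

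Replicate numbers did not pair the samples: in 0 of 34 comparisons was every correlation of same-numbered deviations over 0.1 (-0.366 to 0.403 over 104 pairs, median -0.016). A fit of only the groups compared over the numbers they share, of per-sample values under median-ratio scaling and with the number as a replicate block, changed these choices together. It gave 31 for nitrate against ammonium, 1 and 14 for Δamn-1 in isoleucine and tryptophan, 243 for Δnit-2 in isoleucine, 64 and 778 for the libraries labelled Δnit-4 in nitrate and without nitrogen, 36 for Δnmr without nitrogen, and 63 and 310 for the differences between media of the libraries labelled Δnit-4 and Δnmr. Of the gene lists 8 passed; 157 did with a preset correlation and 1, not among the 8, in fits of only the groups compared, which held fewer samples. With the deleted gene, a nitrogen regulator, left out of the lists 3 did. Per-sample values moved the share of higher calls by over 10 points in 19 comparisons and median-ratio scaling in 1. The median over genes passed 0.1 log2 in 18 comparisons with per-sample values (-0.18 to 0.434) and in 1 with the joint table. Depth limits genes near 1 FPKM, whose differences the pseudocount understates.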

Other observations

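All genes below were chosen after their values were seen, by limma calls in each medium of a strain or by low levels in several strains. In Δnit-2, 39 genes were called lower and 12 higher than in wild type in all 5 media. Among the lower ones NCU01348 differed by -5.70 to -8.89 log2 over the media, NCU06416 by -5.0 to -6.92, its neighbour by number NCU06417 by -2.28 to -3.89, NCU04435 by -3.35 to -4.97 and NCU08407 by -3.55 to -4.61. Of the 39 lower genes 23 were called higher and 0 lower in Δnmr in full medium, and 1 higher and 3 lower without nitrogen. In full medium the 5 genes named were called higher in Δnmr than in wild type, by 2.22, 2.94, 2.67, 3.85 and 1.65 log2 in the same order, and without nitrogen they differed by -0.64, 0.39, 0.56, -0.40 and 0.53, short of the 1 log2 limit. NCU08397, lower in Δnit-2 by -3.78 to -5.19, was not called in Δnmr in full medium (-0.37) and was called lower there without nitrogen (-1.37).

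In Δamn-1, 11 genes were called lower than in wild type in all 4 media, among them NCU02704 (-3.99 to -6.43 log2), the neighbours by number NCU02126 (-1.90 to -4.10) and NCU02127 (-1.92 to -3.73), NCU02936 (-2.33 to -4.81) and NCU00995 (-2.46 to -4.18). In the libraries labelled Δnit-4 176 genes were lower and 76 higher in both media (75 and 117 with per-sample values), and in Δnmr 61 and 32.

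NCU09968 was at 17.9 to 19.7 FPKM in the 3 Δnit-2 libraries of full medium, at 7.35 to 46.2 in wild type and at 6.09 to 26.8 in Δamn-1. It was at 0 to 0.0566 in the other 12 Δnit-2 libraries and at 0 to 0.0163 in the Δnmr libraries and those labelled Δnit-4. NCU09969 was at 5.05 to 5.72, 1.21 to 21.8, 0.455 to 2.77 and 0 to 0.0334 in the first 4 of these sets and listed at 0 in the last.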
